A study of Homo sapiens with 12 samples.

How the data were processed

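RNA sequencing was measured in 12 samples of microglia-like cells that had been derived from an induced pluripotent stem cell line, a wild-type line of the AICS collection per the labels. Per the labels' protocols, blood progenitors were made with a commercial kit and patterned to microglia with IL34 and the growth factor that the labels write as mCSF. Preformed fibrils of amyloid beta (1-42) were then added to cultures of these cells alone, and polyA-selected libraries were made from column-purified RNA. The samples were grouped by the time with fibrils in the titles: a control group at 0 h, called baseline here, and treated groups at 4 h, 24 h and 96 h, with 3 samples each, lettered A to C. The library label of baseline sample A differs in pattern from those of the other 11 samples, and the labels do not say whether it marks another batch. Without this sample 5203, 7283 and 5567 genes passed at 4 h, 24 h and 96 h. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The labels give no untreated group at a later time, so treatment and time in culture cannot be separated in any comparison with baseline.

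The authors deposited TPM, a transcript abundance scaled to the same total in every sample, for each Ensembl transcript in each sample. Per the submitters' processing notes the tool was kallisto and the genome hg38, while the version of kallisto and the annotation release are not given in the sources used here. The deposited table held 143626 transcripts, none of them at 0 in all 12 samples, and each column summed to 1000000. TPM keeps no record of the number of reads, so the sequencing depth is unknown and no counting error could be given.

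Transcripts were assigned to genes through GENCODE release 29 (Ensembl release 94) for hg38, from which the positions of genes were also taken. Of the transcripts, 132176 (92.0%) were on the primary assembly in that release. The other 11450 were not, and 10140 of these had a gene symbol in the reference name table. TPM was summed per gene over both kinds, which gave 27703 genes, and 1310 transcripts without a gene were left out. Transcripts off the primary assembly carried between 2.06% and 3.44% of the TPM of a sample. Genes of the major histocompatibility complex and the CCL3 and CCL4 families had large shares of such TPM. Their values, and those of the closely similar metallothionein and HLA genes and of GIMAP1 and its readthrough GIMAP1-GIMAP5, are uncertain because reads can be split among copies.

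Genes with a TPM of at least 1 in at least 3 samples were tested, which kept 13092 genes and left out 14611. The test was limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a pseudocount of 1 TPM, a mean-variance trend, all 12 samples in the fit and group as the sole term, which left 8 residual degrees of freedom (12.6 with the prior). P-values were two-sided and adjusted by the Benjamini-Hochberg method for each comparison, with a threshold of 0.05. Changes are given as log2 changes of TPM + 1 with the standard error (SE) of limma, a scale that understates the change of genes with low TPM. Levels are given as mean TPM with the standard deviation (SD) over 3 samples.

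A moderated F test of limma covered the 3 comparisons with baseline together. Genes were also put in 3 classes by their tests. Early transient genes changed at 4 h, did not pass at 96 h, and differed between 96 h and 4 h in the opposite direction. Sustained genes changed the same way at all 3 times. Late genes did not pass at 4 h, changed at 96 h, and differed between 96 h and 4 h in the same direction. Gene lists of pathways, complexes and cell types were fixed before the data were examined, 42 in number, and 39 of them had at least 5 tested members. They were compared with all other tested genes by limma's camera with a preset correlation between genes of 0.01, adjusted over the 39 lists of each comparison, and again with a correlation estimated from the data.

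The groups, tests, lists and the rule for the genes named were set before the data were examined. For each comparison with baseline the rule took the 6 protein-coding genes with the largest rise and the 6 with the largest fall that passed the test, reached a mean of 5 TPM in the higher group and did not overlap between the groups, a separation that chance gives for 10% of genes with 3 samples against 3. It added up to 3 members with the lowest adjusted p of each list that passed, and the 4 genes with the largest change of each class and direction. For the classes this change was taken at 4 h for early transient genes and at 96 h for late genes. For sustained genes it was the smallest of the 3 changes. The rule also took a panel of genes at every time whatever their p-value. Those reported here are TREM2, APOE, P2RY12, CX3CR1, TMEM119, CSF1R, SPP1, GPNMB, LPL, CD9, IL1B, TNF, CCL3, CXCL8 and ABCA1. The text does not give every gene taken by the rule, nor each of them at every time.

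The test was checked on simulated data for the comparison of 4 h with baseline, with 13092 genes. It recovered 32 of 50 genes set to a log2 change of 0.5, 35 of 50 set to -0.5, 48 of 50 set to 1 and 49 of 50 set to 2. It called 8 of 12251 unchanged genes, and no list at 24 h, where no change had been set. The simulated genes varied independently of each other, so this does not show how the list test fares with correlated genes. The genes of the recovery counts were drawn from genes above a set baseline level and outside the lists. Recovery of genes with low TPM at baseline was therefore not checked. The alternatives tried were other pseudocounts and filters, median-of-ratios scaling, quantile normalization, TPM rescaled over nuclear protein-coding genes, other settings of limma, other thresholds, the letters A to C as a block, an estimated correlation for lists, and each sample left out in turn. Transcripts of the primary assembly alone, lists between treated times, and a division of the baseline samples between comparisons were added after the data had been seen.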

Results

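The transcriptome of human microglia-like cells derived from induced pluripotent stem cells was measured before fibrils of amyloid beta were added and 4 h, 24 h and 96 h afterwards, with 3 samples at each time. The study asked how the expression of these cells differs between baseline and fibril treatment. Each sample had a TPM of at least 1 for between 11765 and 12445 genes, and depth is unknown because the deposited values are TPM. Across the tested genes, samples of the same group correlated with r between 0.9859 and 0.9902 (12 pairs) and samples of different groups with r between 0.8565 and 0.9553 (54 pairs), where genes are not independent replicates. The first principal component held 57.1% of the variance and the second 20.4%. The share of TPM from mitochondrial genes lay between 12.82% and 14.59% at baseline, 17.26% and 18.33% at 4 h, 9.16% and 13.48% at 24 h, and 15.31% and 22.07% at 96 h. The 10 most abundant genes of a sample held between 16.1% and 25.54% of its TPM.

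**Figure D1:**
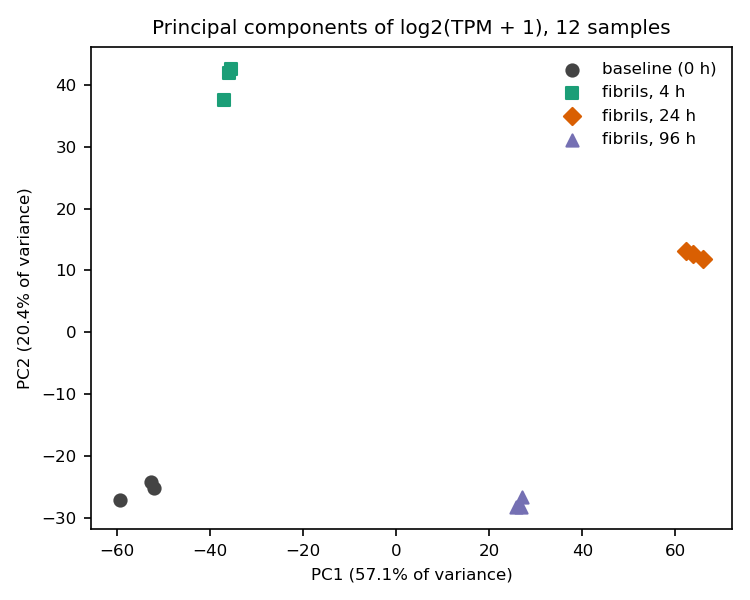
Each point is 1 sample placed by its scores on the first 2 principal components of log2(TPM + 1) over the tested genes (axes in score units, with the percentage of variance), coloured by time with fibrils. The 3 samples of each group lie together, and the first component, with 57.1% of the variance, separates baseline and 4 h from 24 h and 96 h.

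At 4 h the cells carried far more RNA of inflammatory signals than at baseline. CXCL8, a chemokine that attracts neutrophils (chromosome 4, 73740506 to 73743716), rose from 15.1 TPM ± 2.5 (SD, n = 3) to 3160 TPM ± 600 (SD, n = 3), a log2 change of 7.61 (SE 0.16). The related chemokines CXCL3, CXCL2 and CXCL1 rose by 6.45 (SE 0.14), 6.29 (SE 0.16) and 6.17 (SE 0.11). IL1B, the cytokine interleukin 1 beta (chromosome 2, 112829751 to 112836903), rose from 33.1 TPM ± 8.7 to 1560 TPM ± 70. TNF, the cytokine tumour necrosis factor, rose from 56.7 TPM ± 4.3 to 595 TPM ± 53. CCL4, a chemokine that attracts monocytes, rose from 80.6 TPM ± 14 to 5320 TPM ± 140, with 93.68% of its TPM on transcripts off the primary assembly, and its log2 change was 6.04 with them and 3.42 without. Adjusted p (limma, Benjamini-Hochberg) was 3.3e-12 for CXCL8, 1.2e-10 for IL1B, 3.4e-10 for TNF and 2.3e-12 for CCL4.

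All 30 tested NF-kB targets rose at 4 h, with a median log2 change of 2.56 (camera, adjusted p = 5.1e-41, and adjusted p = 0.041 with an estimated correlation). Among them were TNFAIP6, a hyaluronan-binding protein, from 0.583 TPM ± 0.23 to 66.1 TPM ± 13, CD83, an activation marker, from 23.2 TPM ± 0.63 to 302 TPM ± 31, and IRAK2, a kinase of Toll-like receptor signalling, by 3.64 (SE 0.12). Of 24 chemokines 19 rose and 5 did not pass (adjusted p = 2.8e-22, and adjusted p = 0.041 with an estimated correlation). Of 16 pro-inflammatory cytokines 13 rose and 3 did not pass (adjusted p = 1.8e-12, and adjusted p = 0.093 with an estimated correlation). IL1A rose from 0.146 TPM ± 0.032 to 21.7 TPM ± 4.0. Among 25 immediate-early genes, 19 rose and 4 fell (adjusted p = 6e-10, and adjusted p = 0.36 with an estimated correlation), with MAFF, a small transcription factor, up by 3.47 (SE 0.11) and BTG2, an antiproliferative gene, by 1.81 (SE 0.11).

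Of 22 genes of the NRF2 oxidative stress response 12 rose and 4 fell (adjusted p = 2.1e-05, and adjusted p = 0.57 with an estimated correlation). SRXN1, which repairs oxidised peroxiredoxin, rose by 1.90 (SE 0.11), and SQSTM1, an autophagy receptor, from 497 TPM ± 25 to 1420 TPM ± 86. Of 20 genes of the ATF4 stress response 10 rose and 2 fell (adjusted p = 4.3e-05, and adjusted p = 0.48 with an estimated correlation), with ATF3 up by 2.31 (SE 0.13) and DDIT4 by 1.83 (SE 0.11). Of 24 genes of lipid droplets and fatty acid handling 7 rose and 4 fell (adjusted p = 0.0012, and adjusted p = 0.3 with an estimated correlation). ACSL1, which activates fatty acids, rose by 3.06 (SE 0.11), PLIN2, a lipid droplet coat protein, by 0.85 (SE 0.08), and LPL, which releases fatty acids from lipoproteins, by 1.44 (SE 0.12). Of 13 genes of the mitochondrial genome 4 rose and none fell (adjusted p = 0.00014, and adjusted p = 0.73 with an estimated correlation), with MT-ATP8 up by 0.52 (SE 0.12). That rise was 0.17 after quantile normalization, where it did not pass (adjusted p = 0.26, range over the alternatives 0.0022 to 0.26), and neither did the list (adjusted p = 0.43, range 8.2e-05 to 0.73).

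Genes of resting microglia were mostly lower at 4 h. Of 22 homeostatic microglia genes 17 fell and 2 rose (adjusted p = 0.0029, and adjusted p = 0.68 with an estimated correlation). ADORA3, an adenosine receptor, fell from 68.0 TPM ± 4.8 to 3.13 TPM ± 0.98 and GPR34, a receptor of lysophosphatidylserine, from 275 TPM ± 22 to 97.7 TPM ± 4.7. P2RX7, a channel opened by extracellular ATP, rose from 6.2 TPM ± 0.78 to 34.4 TPM ± 5.6. CX3CR1, the receptor of fractalkine, fell by 1.87 (SE 0.16), CSF1R, the receptor of CSF1 and IL34, by 1.04 (SE 0.17), and TMEM119 by 0.71 (SE 0.17). GPNMB, a glycoprotein of lysosomes and the cell surface, fell by 0.61 (SE 0.10). GPNMB, TREM2, SPP1, APOE and CD9 belong to the list of disease-associated and lipid-associated microglia, not to the homeostatic list. TREM2, a lipid receptor of microglia (chromosome 6, 41158506 to 41163186), went from 293 TPM ± 20 to 195 TPM ± 7.4, a log2 change of -0.58 (SE 0.17, adjusted p = 0.014). With median-of-ratios scaling it was -0.38 and did not pass (adjusted p = 0.15, range over the alternatives 0.0068 to 0.15). The fall of P2RY12, an ADP receptor near 1 TPM, went from -0.51 (SE 0.16, adjusted p = 0.02) to -0.41 (adjusted p = 0.065, range 0.009 to 0.18). SPP1, which encodes osteopontin, rose from 803 TPM ± 230 to 4200 TPM ± 110. APOE, CD9 and ABCA1 did not pass, at -0.33, 0.04 and 0.20. ABCA1 passed with median-of-ratios scaling (0.38, adjusted p = 0.0087, range 0.0042 to 0.63), and APOE with the letters as a block (adjusted p = 0.042, range 0.028 to 0.47).

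Of 24 myeloid transcription factors 12 rose and 6 fell (adjusted p = 0.0016, and adjusted p = 0.73 with an estimated correlation). IRF8 rose by 1.57 (SE 0.09) and CEBPD by 1.69 (SE 0.11), and MAF, a factor of resident macrophages, fell by 3.06 (SE 0.12). Of 14 monocyte and macrophage markers 11 fell and none rose (adjusted p = 0.03, and adjusted p = 0.68 with an estimated correlation), among them LYVE1, a hyaluronan receptor, MRC1, the mannose receptor, and F13A1, a subunit of a clotting factor, by 1.07 (SE 0.13), 0.81 (SE 0.11) and 0.80 (SE 0.12). With a filter of 5 TPM this list did not pass by camera (adjusted p = 0.058, range 0.0015 to 0.68), with its median still at -0.66. Of 45 nuclear genes of oxidative phosphorylation 22 fell and none rose (adjusted p = 0.036, and adjusted p = 0.94 with an estimated correlation), a call that ended with median-of-ratios scaling, where the median was -0.02 (adjusted p = 0.71, range 2.7e-05 to 0.94). ATP5F1A, a subunit of ATP synthase, fell by 0.52 (SE 0.08), NDUFB10 by 0.49 (SE 0.08) and NDUFS3 by 0.45 (SE 0.08). NDUFS3 was at -0.24 with median-of-ratios scaling and did not pass (adjusted p = 0.053, range 0.00061 to 0.053). The other large falls were of IRF2BP2, a transcriptional corepressor, by 3.79 (SE 0.18), and of the GTPase genes GIMAP1 and GIMAP6 and the readthrough GIMAP1-GIMAP5, by 3.23 (SE 0.11), 3.14 (SE 0.13) and 3.38 (SE 0.13). Adjusted over the list alone, counts at 4 h matched these except 20 chemokines higher, 4 ATF4 genes lower, 7 myeloid transcription factors lower and 2 mitochondrial genes higher.

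In all, 6086 of the 13092 genes passed at 4 h, 1516 higher and 4570 lower (24.9% higher). The median change of all tested genes was -0.193, and with median-of-ratios scaling, which sets it near 0, 5332 genes passed, 2591 higher and 2741 lower (48.6% higher). Of the 39 lists 12 passed, 2 of them with an estimated correlation. Of these 2 the chemokines did not pass with an estimated correlation and median-of-ratios scaling together (adjusted p = 0.11), though they did with that scaling and the preset correlation (adjusted p = 1.3e-15). Another split of the same 6 samples called as many as 14 lists, so the list calls at 4 h do not stand out from those of other splits. The counts of list members come from the same samples and do not settle this. They are to be read beside the counts of all genes, 1516 higher and 4570 lower as reported.

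At 24 h the inflammatory genes were joined by interferon and metal-binding genes, and cell cycle and ribosomal protein genes were lower. MT1G, a zinc-binding metallothionein (chromosome 16, 56666731 to 56668065), rose from 0.933 TPM ± 0.81 (SD, n = 3) to 4030 TPM ± 440 (SD, n = 3), a log2 change of 11.13 (SE 0.30, limma adjusted p = 6.6e-12), though metallothionein copies share reads. CXCL8 stood at 14700 TPM ± 2700, IL1B at 6300 TPM ± 1100 and IL6, the cytokine interleukin 6, at 907 TPM ± 72 against 2.53 TPM ± 0.92 at baseline. F13A1 (chromosome 6, 6144085 to 6321013) fell from 1230 TPM ± 33 to 1.25 TPM ± 0.34 (adjusted p = 3e-14), and TREM2 from 293 TPM ± 20 to 6.66 TPM ± 2.1, a log2 change of -5.30 (SE 0.17, adjusted p = 3.1e-11).

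Of 37 genes of the type I interferon response 36 rose at 24 h, with a median of 2.93 (adjusted p = 1.9e-22, and adjusted p = 0.19 with an estimated correlation). IFIT1, an antiviral protein, rose from 12.3 TPM ± 3.1 to 447 TPM ± 37, USP18, which limits interferon signalling, by 4.83 (SE 0.17), and DDX58, a sensor of viral RNA, by 2.93 (SE 0.10). Of 24 chemokines 23 rose (adjusted p = 4.7e-20, and adjusted p = 0.11 with an estimated correlation), with CCL7, which attracts monocytes, from 0.407 TPM ± 0.10 to 388 TPM ± 30. Of 30 NF-kB targets 28 rose (adjusted p = 5e-19, and adjusted p = 0.13 with an estimated correlation), with TNFAIP6 up by 8.11 (SE 0.17) and ZC3H12A, an RNase that degrades cytokine mRNA, by 4.54 (SE 0.13). Of 16 cytokines 14 rose (adjusted p = 4.1e-10, and adjusted p = 0.13 with an estimated correlation), and TNF was at 165 TPM ± 20. Of 10 metallothionein and zinc genes 9 rose and 1 fell (adjusted p = 1.5e-09, and adjusted p = 0.13 with an estimated correlation). MT2A rose from 3.18 TPM ± 0.38 to 2320 TPM ± 340, and MT1M, listed at 0 in every baseline sample, was at 265 TPM ± 30. Of 19 genes of MHC class I presentation 15 rose and 2 fell (adjusted p = 5.7e-07, and adjusted p = 0.3 with an estimated correlation), with TAP1, a peptide transporter, up by 2.31 (SE 0.13) and PSME2, a proteasome activator, by 1.88 (SE 0.09).

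All 40 cell cycle genes fell at 24 h, with a median of -1.85 (adjusted p = 3.2e-15, and adjusted p = 0.19 with an estimated correlation). TOP2A, which untangles DNA at mitosis, fell by 3.63 (SE 0.14), and TK1 and TYMS, enzymes of thymidine nucleotide synthesis, by 2.47 (SE 0.09) and 2.51 (SE 0.10). Of 70 cytosolic ribosomal protein genes 68 fell and none rose, with a median of -1.02 (adjusted p = 6.2e-17, and adjusted p = 0.37 with an estimated correlation), RPL3 from 1490 TPM ± 29 to 458 TPM ± 20. Of 25 ribosome biogenesis genes 19 fell (adjusted p = 0.0029, and adjusted p = 0.62 with an estimated correlation), with FBL, which methylates ribosomal RNA, down by 1.45 (SE 0.09). Of 45 oxidative phosphorylation genes 32 fell and 1 rose (adjusted p = 6e-05, and adjusted p = 0.6 with an estimated correlation), with ATP5MC1 down by 1.40 (SE 0.07). Of 24 cholesterol biosynthesis genes 17 fell and 2 rose (adjusted p = 0.0093, and adjusted p = 0.62 with an estimated correlation), with ACAT2 falling from 105 TPM ± 5.7 to 9.81 TPM ± 0.15.

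Of 22 homeostatic microglia genes 18 fell and 2 rose at 24 h (adjusted p = 8.6e-05, and adjusted p = 0.37 with an estimated correlation). GAS6, a ligand of TAM receptors that aid the uptake of dying cells, fell from 178 TPM ± 25 to 4.16 TPM ± 1.0, and GPR34 by 3.28 (SE 0.10). P2RY12, CX3CR1 and CSF1R fell by 1.21 (SE 0.16), 1.80 (SE 0.16) and 0.76 (SE 0.17), and TMEM119 did not pass at -0.26 (SE 0.17). GPNMB fell by 1.74 (SE 0.10) and CD9, a tetraspanin, by 2.12 (SE 0.15), while SPP1 and LPL rose by 3.52 (SE 0.24) and 1.03 (SE 0.12). The other largest falls were of AGR2, a disulfide isomerase, from 166 TPM ± 14 to 0.0954 TPM ± 0.069, SELENOP, a selenium carrier, from 1260 TPM ± 14 to 32.6 TPM ± 7.3. LYVE1 fell by 5.45 (SE 0.13), and HLA-DMB, which loads peptides on MHC class II, fell by 5.56 (SE 0.10), with 81.99% of its TPM off the primary assembly. C15orf48, a relative of a subunit of mitochondrial cytochrome oxidase, rose from 5.67 TPM ± 1.4 to 3070 TPM ± 290.

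Of 17 LXR targets and cholesterol efflux genes 10 rose and 3 fell at 24 h (adjusted p = 0.0026, and adjusted p = 0.37 with an estimated correlation). NR1H3, which encodes LXR alpha, rose from 52.0 TPM ± 4.3 to 549 TPM ± 55, and ABCA1, a cholesterol exporter, by 1.53 (SE 0.13). APOE, the main lipid carrier of glia, was at 239 TPM ± 47 against 188 TPM ± 5.4 and did not pass (0.33, SE 0.14, adjusted p = 0.053). With median-of-ratios scaling it passed at 0.53 (adjusted p = 0.0024, range over the alternatives 0.0024 to 0.25). Of 22 NRF2 genes 12 rose and 5 fell (adjusted p = 0.013, and adjusted p = 0.62 with an estimated correlation), with FTH1, the ferritin heavy chain, up by 2.09 (SE 0.10) and GCLC, of glutathione synthesis, down by 2.25 (SE 0.08). This call ended with quantile normalization (adjusted p = 0.11, range 0.0033 to 0.62) and with a filter of 5 TPM (adjusted p = 0.055), with medians of 0.48 and 0.50 against 0.54. Of 25 immediate-early genes 15 rose and 5 fell (adjusted p = 0.0011, and adjusted p = 0.6 with an estimated correlation), with FOSL2 up by 3.83 (SE 0.15). Of 17 secretory and amyloid-degrading proteases 10 rose and 5 fell (adjusted p = 0.03, and adjusted p = 0.62 with an estimated correlation), and MMP1, a collagenase, rose by 4.39 (SE 0.22). PLAU, the urokinase, fell by 3.87 (SE 0.13).

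Some markers of other cell types were higher at 24 h, among the few that were tested. Of 5 tested granulocyte and mast cell markers, of 18 listed, 4 rose and 1 fell (adjusted p = 0.011, and adjusted p = 0.19 with an estimated correlation). S100A8 and S100A9, calcium-binding proteins that the monocyte list also holds, rose from 48.8 TPM ± 12 to 2680 TPM ± 610 and from 1660 TPM ± 230 to 7930 TPM ± 1100. Of 7 tested neural markers, of 16 listed, 4 rose and 1 fell (adjusted p = 0.044, and adjusted p = 0.3 with an estimated correlation). OLIG2, a transcription factor of the oligodendrocyte lineage (chromosome 21, 33025845 to 33029196), rose from 0.0981 TPM ± 0.079 to 37.9 TPM ± 8.9, and S100B, a calcium-binding protein of glia, from 222 TPM ± 35 to 1330 TPM ± 160. With median-of-ratios scaling the calls of the protease (adjusted p = 0.08, range 0.006 to 0.62), granulocyte (adjusted p = 0.061, range 0.0076 to 0.19) and neural lists (adjusted p = 0.097, range 0.031 to 0.3) ended. Their medians were 0.71, 2.25 and 0.81 before and 0.91, 2.45 and 0.93 after. Without the filter, which a gene such as OLIG2 passes only through its treated samples, the granulocyte median was 0 (adjusted p = 0.059) and the neural median -0.02 (adjusted p = 0.21), and neither passed. Adjusted over the list alone, counts at 24 h matched except 1 cytokine lower, 3 MHC class I genes lower, 18 cholesterol genes lower, 11 LXR genes higher, and 13 NRF2 genes higher and 6 lower.

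At 24 h 8014 genes passed, 3029 higher and 4985 lower (37.8% higher). The median change of all genes was -0.165, and with median-of-ratios scaling 8230 passed, 4161 higher and 4069 lower (50.6% higher). Of 39 lists 18 passed, and by camera with an estimated correlation 0 did, with 7 at an unadjusted p under 0.05. Another split of the same samples called as many as 17 lists, so the number of lists at 24 h stands out little.

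**Figure D2:**
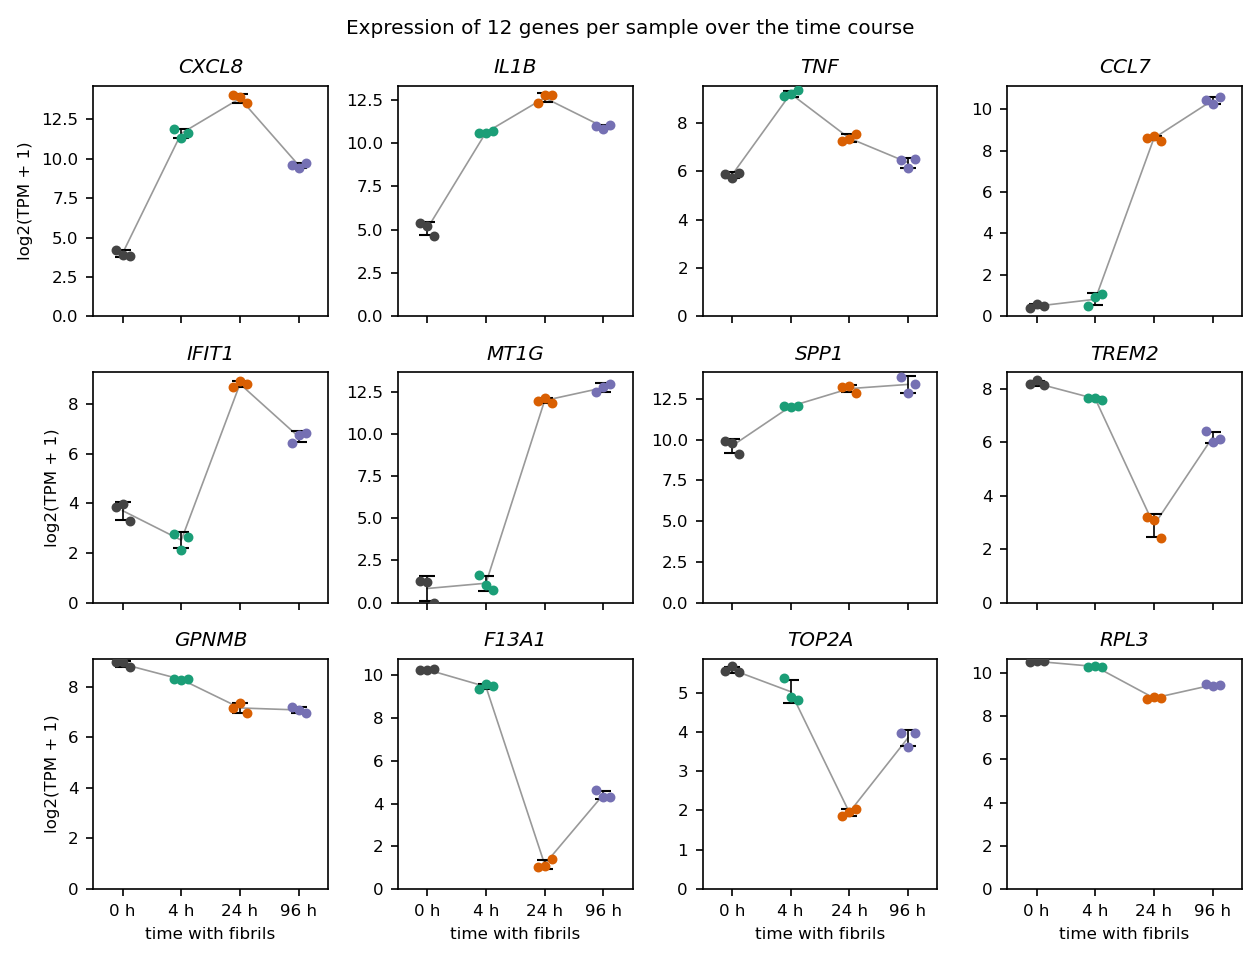
Expression of 12 genes as log2(TPM + 1) against time with fibrils, with a point for each of 3 samples per time, bars for the mean ± SD and lines between means. CXCL8 and IL1B were highest at 24 h, TNF at 4 h and CCL7 at 96 h, while TREM2, F13A1 and TOP2A were lowest at 24 h.

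At 96 h metallothioneins and chemokines were still higher than at baseline, and ribosomal protein genes were still lower. MT1G was at 6870 TPM ± 1200 (SD, n = 3) against 0.933 TPM ± 0.81, a log2 change of 11.89 (SE 0.30, limma adjusted p = 1e-11). CCL7 (chromosome 17, 34270221 to 34272242) was at 1390 TPM ± 160 against 0.407 TPM ± 0.10 (9.94, SE 0.14, adjusted p = 7.1e-14). SPP1 reached 11100 TPM ± 3700, a rise of 3.77 (SE 0.24), and APOE 400 TPM ± 28, a rise of 1.08 (SE 0.14). TREM2 stood at 72.1 TPM ± 11, a change of -2.01 (SE 0.17, adjusted p = 7.2e-07), and AGR2 (chromosome 7, 16791811 to 16833433) at 0.356 TPM ± 0.11 against 166 TPM ± 14.

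Of 10 metallothionein and zinc genes 9 were higher at 96 h (adjusted p = 1.5e-14, and adjusted p = 0.049 with an estimated correlation), MT1X by 6.71 (SE 0.11) and MT2A by 8.61 (SE 0.15), with MT1M at 329 TPM ± 66 against a listed 0. Of 24 chemokines 22 were higher (adjusted p = 1.4e-18, and adjusted p = 0.049 with an estimated correlation), CXCL1 by 4.67 (SE 0.11) and CXCL5 by 5.86 (SE 0.16). CXCL8 and CCL3 were higher by 5.59 (SE 0.16) and 2.46 (SE 0.10). Of 37 interferon genes 34 were higher (adjusted p = 7.2e-18, and adjusted p = 0.26 with an estimated correlation), IFI27 from 197 TPM ± 14 to 2110 TPM ± 280. Of 30 NF-kB targets 23 were higher and 2 lower (adjusted p = 4.9e-12, and adjusted p = 0.26 with an estimated correlation), with BCL2A1, which inhibits apoptosis, up by 4.87 (SE 0.21). Of 16 cytokines 10 were higher (adjusted p = 7.6e-06, and adjusted p = 0.26 with an estimated correlation), IL1B at 1950 TPM ± 150, IL6 at 48.7 TPM ± 7.6 and TNF at 82.0 TPM ± 12. Of 19 MHC class I genes 11 were higher and 3 lower (adjusted p = 0.0014, and adjusted p = 0.65 with an estimated correlation), with PSMB9, an immunoproteasome subunit, up by 1.53 (SE 0.17), or 0.82 with transcripts of the primary assembly alone. Of 17 proteases 10 were higher and 4 lower (adjusted p = 0.02, and adjusted p = 0.73 with an estimated correlation), with ADAM10 up by 1.48 (SE 0.14).

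All 70 ribosomal protein genes were lower at 96 h, with a median of -0.72 (adjusted p = 1.8e-19, and adjusted p = 0.44 with an estimated correlation), RPLP0 by -1.11 (SE 0.06) and RPL6 by -0.96 (SE 0.07). Of 25 ribosome biogenesis genes 14 were lower (adjusted p = 0.024, and adjusted p = 0.79 with an estimated correlation), with NPM1 at -0.71 (SE 0.09). Of 45 oxidative phosphorylation genes 34 were lower and none higher (adjusted p = 6.3e-07, and adjusted p = 0.61 with an estimated correlation), SDHA, of succinate dehydrogenase, by -1.06 (SE 0.09). Of 43 lysosome genes 29 were lower and 7 higher (adjusted p = 0.0011, and adjusted p = 0.73 with an estimated correlation), CTSC, a protease, from 822 TPM ± 51 to 232 TPM ± 15, and ASAH1, an acid ceramidase, from 567 TPM ± 24 to 158 TPM ± 13. Of 24 cholesterol biosynthesis genes 15 were lower and 1 higher (adjusted p = 0.0025, and adjusted p = 0.73 with an estimated correlation), TM7SF2 by -1.37 (SE 0.12). Of 40 cell cycle genes 20 were lower and 1 higher (adjusted p = 0.015, and adjusted p = 0.79 with an estimated correlation), TOP2A by -1.73 (SE 0.14). Without treated sample B the list did not pass (adjusted p = 0.061, range 0.00024 to 0.79), nor did ribosome biogenesis (adjusted p = 0.073, range 9e-04 to 0.79).

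Of 22 homeostatic microglia genes 14 were lower and 2 higher at 96 h (adjusted p = 0.0024, and adjusted p = 0.65 with an estimated correlation), with TGFBR1, a receptor of TGF-beta, at -1.97 (SE 0.10) and P2RY12 at -1.17 (SE 0.16). CX3CR1, TMEM119, CSF1R and CD9 did not pass, at -0.33, 0.27, -0.28 and -0.36. TMEM119 passed with median-of-ratios scaling (0.39, adjusted p = 0.042, range 0.042 to 0.44), and CD9 in 4 of 15 alternatives (adjusted p range 0.019 to 0.29). GPNMB was lower by -1.82 (SE 0.10), LPL by -0.55 (SE 0.12), and ABCA1 was higher by 0.70 (SE 0.13). Among the largest falls were LTC4S, which makes leukotriene C4, from 74.5 TPM ± 6.8 to 0.856 TPM ± 0.48, CYTL1, a secreted protein, from 102 TPM ± 3.4 to 1.69 TPM ± 0.53, and FOLR2, a folate receptor, from 371 TPM ± 7.4 to 13.7 TPM ± 1.6. Of 13 mitochondrial genome genes 6 were higher and none lower (adjusted p = 0.0025, and adjusted p = 0.73 with an estimated correlation), MT-ND2 by 0.67 (SE 0.16) and MT-CO1 by 0.48 (SE 0.14). Quantile normalization turned both the list median (-0.01, adjusted p = 0.98, range 3.2e-05 to 0.98) and MT-CO1 (-0.16, adjusted p = 0.033, range 0.0022 to 0.12). Without treated sample B, whose mitochondrial share of 22.07% was the highest, MT-CO1 was at 0.36 and did not pass (adjusted p = 0.057).

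Of the 7 tested neural markers, of 16 listed, 6 were higher at 96 h and none was lower (adjusted p = 4.4e-05, and adjusted p = 0.049 with an estimated correlation), with OLIG2 at 22.5 TPM ± 1.7, S100B at 1310 TPM ± 130 and TUBB3, a tubulin of neurons, at 7.37 TPM ± 0.21 against 1.47 TPM ± 0.30. Of 5 granulocyte and mast cell markers 3 were higher and 1 lower (adjusted p = 0.019, and adjusted p = 0.26 with an estimated correlation), with S100A8 at 1170 TPM ± 150. The calls of the granulocyte (adjusted p = 0.083, range 0.011 to 0.26) and protease lists (adjusted p = 0.053, range 0.01 to 0.73) ended with median-of-ratios scaling, with medians of 2.22 and 0.54 before and 2.35 and 0.68 after. Without the filter the granulocyte median was 0 and did not pass (adjusted p = 0.11), and the neural median was also 0, with an adjusted p of 0.0067 (range 2.1e-05 to 0.049). Adjusted over the list alone, counts at 96 h matched except 24 NF-kB targets, 35 interferon genes, 12 MHC class I genes and 10 mitochondrial genes higher, and 1 interferon gene, 31 lysosome, 17 cholesterol, 21 cell cycle and 16 ribosome biogenesis genes lower.

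At 96 h 6339 genes passed, 2412 higher and 3927 lower (38.1% higher). The median change of all genes was -0.108, and with median-of-ratios scaling 6525 passed, 3339 higher and 3186 lower (51.2% higher). Of 39 lists 17 passed, 3 of them with an estimated correlation, and none of these 3 with an estimated correlation and median-of-ratios scaling together (adjusted p = 0.097 each). With that scaling and the preset correlation all 3 passed. Another split of the same samples called as many as 15 lists, so the number of lists at 96 h stands out little.

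**Figure D3:**
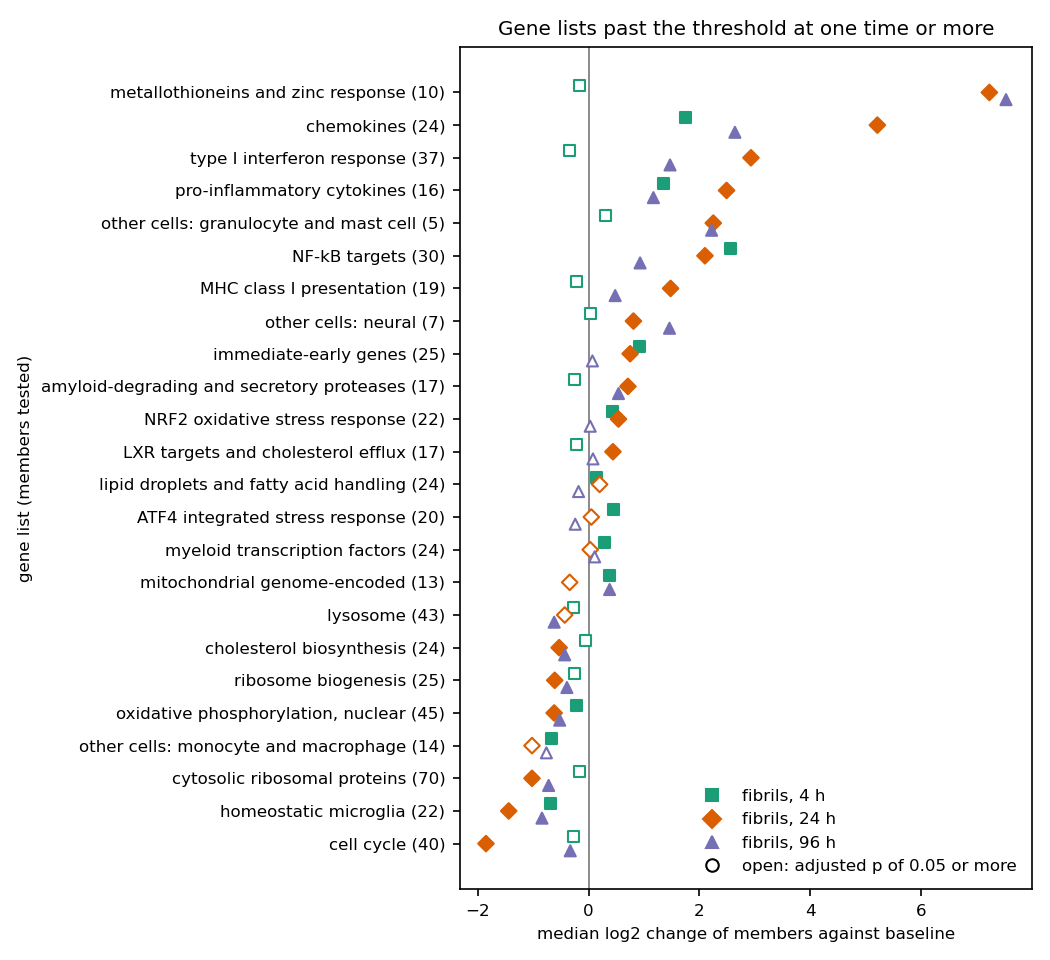
Median log2 change against baseline of the tested members of each of the gene lists that passed at a time or more (number of members in brackets), with 1 symbol per time and open symbols for an adjusted p of 0.05 or more under the preset correlation. Metallothioneins had medians of 7.23 at 24 h and 7.53 at 96 h, and cell cycle genes -1.85 at 24 h and -0.33 at 96 h. The mitochondrial median at 96 h turned to -0.01 under quantile normalization.

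Several lists named for microglia and Alzheimer's disease did not pass at any time as reported. Of 29 tested genes of disease-associated and lipid-associated microglia, 8, 11 and 11 rose and 7, 12 and 14 fell at 4 h, 24 h and 96 h (adjusted p = 0.081, 0.55 and 0.82). Of 31 Alzheimer risk genes expressed in myeloid cells, 3, 12 and 13 rose and 15, 14 and 11 fell (adjusted p = 0.085, 0.81 and 0.67). Of 30 amyloid-binding and scavenger receptors, 4, 11 and 8 rose and 18, 15 and 14 fell (adjusted p = 0.085, 1 and 0.82). With median-of-ratios scaling this list passed at 4 h, with 4 higher and 13 lower (adjusted p = 0.046, and adjusted p = 0.74 with an estimated correlation). Of 20 complement genes, 2, 8 and 5 rose and 7, 7 and 8 fell (adjusted p = 0.9, 0.36 and 0.76), and of 12 MHC class II genes, 0, 2 and 1 rose and 5, 5 and 6 fell (adjusted p = 0.26, 0.48 and 0.12). Median, mean and test differed in sign for the disease-associated genes at 4 h and 24 h, and for the risk, scavenger and complement genes at 24 h and 96 h. The monocyte and macrophage markers, which passed at 4 h, did not pass later: of 14, 5 rose and 8 fell at both 24 h and 96 h (adjusted p = 0.48 and 0.9), and at 96 h their mean was 0.15 and their median -0.76.

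The treated times were compared directly to ask when genes changed. From 4 h to 24 h, CXCL8 rose by a further 2.22 (SE 0.16), IFIT1 rose by 6.29 (SE 0.19) and CCL7 by 7.77 (SE 0.14), while TNF fell by 1.85 (SE 0.12) and TREM2 by 4.72 (SE 0.17). From 24 h to 96 h, CXCL8, IL6 and IL1B fell by 4.24 (SE 0.16), 4.20 (SE 0.18) and 1.68 (SE 0.17). TREM2, F13A1 and CD9 rose by 3.29 (SE 0.17), 3.26 (SE 0.12) and 1.76 (SE 0.15), and TOP2A rose by 1.90 (SE 0.14). Between 24 h and 96 h all 40 cell cycle genes rose (adjusted p = 1.3e-24, and adjusted p = 0.14 with an estimated correlation). Meanwhile 28 of 30 NF-kB targets fell and 1 rose (adjusted p = 5.1e-19, and adjusted p = 0.14 with an estimated correlation), and 35 of 37 interferon genes fell (adjusted p = 1.5e-20, and adjusted p = 0.26 with an estimated correlation), list tests that were added after the data had been seen. Limma called 7818 genes between 4 h and 24 h, 3941 higher and 3877 lower at 24 h. It called 5272 between 24 h and 96 h, 3090 higher and 2182 lower at 96 h, and 7325 between 4 h and 96 h, 4101 higher and 3224 lower at 96 h. The split depends on the scaling. With median-of-ratios scaling it was 4092 and 4131, 2917 and 3015, and 3834 and 3848, and over nuclear protein-coding genes alone 3270 and 4509, 4237 and 1550, and 4192 and 3172.

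Genes were then sorted by the course of their change. TNFRSF18 and TNFRSF4, receptors of the TNF family that costimulate T cells, were early transient, with TNFRSF18 at 43.7 TPM ± 1.8 at 4 h and 0.311 TPM ± 0.25 at 96 h against 0.324 TPM ± 0.058 at baseline. IL1A and CD83 were early transient as well, although IL1A stood at 154 TPM ± 37 at 24 h. At 96 h IL1A passed in 2 of 15 alternatives, among them a pseudocount of 0.1 TPM (1.05, adjusted p = 0.0021, range 0.0021 to 0.35). CD83 passed at 96 h in 5 of 15, among them median-of-ratios scaling (0.42, adjusted p = 0.0051, range 0.0047 to 0.23). A call at 96 h would take these genes out of the early transient class. TNFRSF4 passed at 96 h in 1 of 15 alternatives (range 0.037 to 0.28) and FRAT2 in 2 (range 0.033 to 0.16). The early transient falls were led by GIMAP1-GIMAP5, FRAT2, an inhibitor of GSK3, RGS14, a regulator of G protein signalling, and AC009086.2, at -3.38, -2.73, -2.62 and -2.66. AC009086.2 was near 0 in 4 h sample A alone, and its change was -1.68 without that sample. Ranked by the smallest of their 3 changes, CXCL8, IL1B, TNFAIP6 and C15orf48 led the sustained rises. By the same ranking MAF, ADORA3, DAB2, an endocytic adaptor, and TNFRSF25, a death receptor, led the sustained falls. F13A1 was lower at 24 h and 96 h than at 4 h, with changes of -8.31 (SE 0.12) and -5.05 (SE 0.12), and rose between 24 h and 96 h. MT1G, MT1H, CCL7 and MT1E led the late rises, and IGF1, a growth factor, IL18BP, which neutralises interleukin 18, AC010422.3 and AL132780.3 the late falls. CCL7 passed at 4 h in 5 of 15 alternatives (adjusted p range 0.0047 to 0.24) and MT1E in 1 (range 0.031 to 0.88), which would take them out of the late class. IGF1 was at 31.8 TPM ± 2.1 at baseline and 0.318 TPM ± 0.21 at 96 h.

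The early transient class held 549 genes higher and 1540 lower, the sustained class 580 and 1770, and the late class 1046 and 1319. With median-of-ratios scaling these were 911 and 947, 1018 and 968, and 1430 and 1464. The F test of limma called 10372 genes over the 3 times.

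The responses at the 3 times were compared gene by gene, although they share the same baseline samples. Changes at 24 h and 96 h correlated across genes with r = 0.83 and a covariance of 0.715, those at 4 h and 24 h with r = 0.49 and 0.34, and those at 4 h and 96 h with r = 0.38 and 0.193, where genes are not independent replicates. Unchanged groups simulated around the baseline means, with the baseline drawn anew as well, gave r = 0.50 and a covariance of 0.016. Between 24 h and 96 h 1849 genes were higher at both times, 3208 lower at both and 175 opposite, where independent lists would share 558 and 1495. For 4 h and 24 h these were 871, 2629 and 803 (independent 351 and 1740), and for 4 h and 96 h 648, 1997 and 781 (independent 279 and 1371). Simulated unchanged groups shared on average at most 0.01 genes in each direction. With no change set few genes can pass, so this does not measure how a shared baseline adds to the overlap of changed genes. With the baseline samples divided between the 2 comparisons, 1 and 2 samples, an alternative added after the data had been seen, r lay between 0.77 and 0.79 for 24 h and 96 h, 0.41 and 0.48 for 4 h and 24 h, and 0.29 and 0.36 for 4 h and 96 h. Part of the excess of shared genes may come from the shared baseline, which cannot give 2 samples to each comparison. These correlations and shared counts are of TPM as deposited and were not repeated with median-of-ratios scaling. As deposited, the median change of all genes was -0.193, -0.165 and -0.108 at 4 h, 24 h and 96 h. How far this common shift adds to the genes lower at both times was not tested.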

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

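The tests between treated times were planned before the data were examined, while the choice to take up here only genes that moved in opposite directions at different times was made after the results were seen. Single outlying samples were not tested for in these groups of 3. The naming rule took 140 genes, not all of which are given in the text. Of these, 12 passed limma's test in opposite directions against baseline at different times, and the difference between those times also passed.

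The first 6 of these genes were higher at an earlier time and lower at a later one, which their lists as a whole did not show. LPL was higher at 4 h (1.44) and 24 h (1.03) and lower at 96 h (-0.55), with differences of -1.58 (SE 0.12, adjusted p = 5.8e-07) from 24 h to 96 h and -1.99 (SE 0.12, adjusted p = 4.3e-08) from 4 h to 96 h. PLIN2 went from 0.85 at 4 h to -0.39 at 96 h, a difference of -1.24 (SE 0.08). OSGIN1, an NRF2 target, went from 1.97 at 4 h to -0.98 at 24 h and -1.51 at 96 h, differences of -2.95 and -3.47 (SE 0.12 each). GCLC, of glutathione synthesis, went from 0.44 at 4 h to -2.25 at 24 h and -0.91 at 96 h, differences of -2.69 and -1.35 (SE 0.08 each). Of the transcription factors, IRF8 went from 1.57 at 4 h to -1.14 at 24 h, a difference of -2.71 (SE 0.09), and CEBPD from 1.69 at 4 h to -0.34 at 96 h, a difference of -2.03 (SE 0.11).

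The other 6 were lower at an earlier time and higher at a later one, and no interferon, metallothionein or MHC class I list passed at 4 h (adjusted p = 0.21, 0.93 and 0.9). IFIT1 went from -1.19 at 4 h to 5.10 at 24 h and 2.97 at 96 h, differences of 6.29 and 4.16 (SE 0.19 each). MT1X went from -0.93 at 4 h to 6.41 and 6.71, differences of 7.33 and 7.64 (SE 0.11 each). PSMB8, an immunoproteasome subunit with 83.1% of its TPM off the primary assembly, went from -0.71 to 1.65 and 1.05, differences of 2.36 and 1.76 (SE 0.10 each). APOC2, an activator of LPL, went from -0.51 to 2.01 and 1.96, differences of 2.51 and 2.47 (SE 0.11 each), and S100B from -0.48 to 2.58 and 2.57, differences of 3.07 and 3.05 (SE 0.12 each). MT-CO1, a mitochondrial subunit of cytochrome oxidase, went from -0.55 at 24 h to 0.48 at 96 h, a difference of 1.03 (SE 0.14). With median-of-ratios scaling, CEBPD, APOC2, S100B and MT-CO1 no longer passed in opposite directions, and the other 8 genes still did.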

How the results depend on the processing

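Transcripts of the primary assembly alone, the list tests between treated times and the divided baseline were alternatives added after the data were seen, and all others were planned. Of the counts of genes, lists and classes, those not named here stayed within 1.5 times the reported count under every alternative. With an absolute log2 change of at least 1 also required, which is stricter by construction, genes passing numbered 1052 at 4 h, 2972 at 24 h, 1535 at 96 h, 2496 between 4 h and 24 h, 1156 between 24 h and 96 h, 1770 between 4 h and 96 h, and 3673 by the F test. Lists passing at 4 h numbered 19 with no filter, and the cause was not tested. With an estimated correlation, which was higher than the preset one and so widens the test, 2, 0 and 3 lists passed at 4 h, 24 h and 96 h by camera (5, 7 and 7 at an unadjusted p under 0.05). Leaving out 1 sample at a time gave 5165 to 5442 genes at 4 h, 7283 to 7677 at 24 h, 5521 to 6017 at 96 h, 7031 to 7520, 4393 to 5095 and 6460 to 6859 between 4 h and 24 h, 24 h and 96 h, and 4 h and 96 h, 9905 to 10302 by the F test, 11 to 13, 17 to 21 and 15 to 18 lists, and 1765 to 2141, 1850 to 2442 and 2020 to 2508 genes in the early transient, sustained and late classes. With median-of-ratios scaling 4255 of 6086, 7097 of 8014 and 5595 of 6339 calls were kept in the same direction and none turned, and with quantile normalization 4690, 7285 and 5930 were kept and 2 turned, at 96 h. With primary transcripts alone 6012, 7923 and 6250 were kept and 108 genes were not tested. Signs turned in genes near no change, which reached, with samples left out, 0.09 for CD9, 0.53 for MT1G, 0.26 for MT1H, -0.27 for AL132780.3 and -0.25 for IL18BP at 4 h, and -0.17 for TNFRSF18 and 0.11 for GIMAP1-GIMAP5 at 96 h. Over all alternatives CD9 reached 0.24, MT1G 1.08, MT1H 0.45, TNFRSF18 -0.25 and GIMAP1-GIMAP5 0.16. Under median-of-ratios scaling TNFRSF18 at 96 h was 0, and AL132780.3 and IL18BP at 4 h were 0.03 and 0.08. Under quantile normalization MT1H and IL18BP at 4 h were -0.01 and 0.03, and at 96 h MT-CO1 was -0.16 (adjusted p = 0.033, range 0.0022 to 0.12) and the mitochondrial list -0.01. Without baseline sample A MT1H and AC010422.3 at 4 h were -0.05 and -0.11. Without baseline sample C CD9, MT1G, MT1H, AL132780.3 and IL18BP at 4 h were -0.07, -0.11, -0.05, 0.01 and 0.06, and TNFRSF18 at 96 h 0. Without 4 h sample B MT1H and AC010422.3 at 4 h were -0.05 and -0.08, and at 96 h GIMAP1-GIMAP5 was -0.06 without 96 h sample B and TNFRSF18 0.1 without 96 h sample C. Apart from MT-CO1 and the mitochondrial list these had not passed, and the cause was not tested. Calls lost without 1 sample were MT-ND4L at 4 h without any 1 of the 6 samples (adjusted p 0.061 to 0.13), MT-ND1 at 4 h without baseline B (0.073) or treated C (0.057), P2RY12 at 4 h without treated C (0.094), the monocyte list at 4 h without baseline B (0.075), and oxidative phosphorylation at 4 h without baseline B (0.22) or treated B (0.092) or C (0.14), and at 96 h without treated B the cell cycle list (0.061), ribosome biogenesis (0.073) and MT-CO1 (0.057). Whether the letters A to C pair the samples was left open: 5 of 18 same-letter pairs across groups deviated together with r over 0.1 (-0.056 to 0.157), and the best match had the same letter in 21 of 36 cases, where chance gives 12, and, in every group, for 2 of 12 samples. With the letters as a block 6375, 8217 and 6597 genes passed at 4 h, 24 h and 96 h, and calls gained were APOE at 4 h (adjusted p = 0.042, range 0.028 to 0.47) and 24 h (0.032, range 0.0024 to 0.25), and CD9 (0.026, range 0.019 to 0.29) and FRAT2 (0.033, range 0.033 to 0.16) at 96 h. Depth is unknown, so whether genes near 1 TPM are limited by it could not be judged.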

Other observations

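All tests of explanations in this part were chosen after the results were seen, apart from the test of transcript length and the splits of the samples, and the genes in its first 2 paragraphs were chosen after their values were seen. Single genes of tissue macrophages were lower at 24 h, while the monocyte and macrophage list did not pass there (adjusted p = 0.48). STAB1, a scavenger receptor, went from 2440 TPM ± 460 at baseline (SD, n = 3) to 140 TPM ± 18 at 24 h and 834 TPM ± 99 at 96 h, MRC1 from 68.7 TPM ± 3.1 to 2.1 TPM ± 0.37 and 9.02 TPM ± 1.4, and CD163, the haemoglobin scavenger receptor, from 328 TPM ± 20 to 110 TPM ± 11 and 199 TPM ± 25 (limma, adjusted p = 5.7e-11, 3.4e-12 and 2.3e-08 at 24 h). Among Alzheimer risk genes, MS4A6A fell by 5.20 (SE 0.11) and BIN1, of membrane curvature, by 2.92 (SE 0.09), ABI3 fell by 3.25 (SE 0.16) at 24 h. PICALM, of clathrin endocytosis, rose by 1.11 (SE 0.09) and CTSH, a lysosomal protease, by 1.86 (SE 0.10). TREM1, an amplifier of inflammation, rose from 0.566 TPM ± 0.18 to 34.6 TPM ± 7.5 at 24 h and 24.2 TPM ± 3.1 at 96 h. TYROBP, the adaptor of both TREM receptors, was at -0.26, -0.38 and -0.33 at 4 h, 24 h and 96 h (adjusted p = 0.016, 0.001 and 0.0037) and did not pass at any of these times after median-of-ratios scaling (adjusted p = 0.69, 0.13 and 0.11).

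Receptors reported to bind amyloid moved apart. MARCO, a scavenger receptor, rose from 0.648 TPM ± 0.26 to 8.23 TPM ± 0.72 at 24 h and 89.8 TPM ± 20 at 96 h, and CD36, a fatty acid and scavenger receptor, fell from 189 TPM ± 7.8 to 28.8 TPM ± 5.6 and 98.6 TPM ± 23. TLR2 rose by 1.59 (SE 0.10) and TLR4 fell by 1.42 (SE 0.09) at 4 h. IDO1, which breaks down tryptophan, was listed at 0 in every baseline sample and reached 321 TPM ± 74 at 24 h and 2.06 TPM ± 0.76 at 96 h, and KYNU, of the same pathway, rose from 31.7 TPM ± 3.1 to 489 TPM ± 57 at 24 h. ACOD1, which makes itaconate, was listed at 0 at baseline and reached 18.8 TPM ± 0.45 at 24 h. SLC39A8, a zinc importer, rose from 10.1 TPM ± 0.92 to 235 TPM ± 20 and 275 TPM ± 21 at 24 h and 96 h, and SLC30A1, a zinc exporter, by 1.56 (SE 0.09) and 1.40 (SE 0.09). Of the complement genes, C1QA and C1QC fell by 1.36 (SE 0.09) and 0.91 (SE 0.12) at 24 h, and C3 and CFB rose by 1.02 (SE 0.13) and 1.86 (SE 0.19).

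Chemokine, cytokine and NF-kB genes were higher at 24 h and partly back at 96 h. Of their 70 tested members 59 were lower and 4 higher at 96 h than at 24 h, with a median change of -1.44, which argues against a steady drift with time in culture as the whole cause. A contaminant of the fibril preparation such as endotoxin may be a cause as well as the fibrils: endotoxin also induces interferon genes, and 36 of 37 interferon members rose at 24 h, which either could give. These cannot be told apart, since there is no group with vehicle or another ligand. A change with time in culture that is not steady, and the handling of cells when fibrils were added, stay open as well.

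Ribosomal protein genes were lower at 24 h, with a median change of -1.02. A few induced genes taking a larger share of the TPM may lower all others, but with median-of-ratios scaling the median stayed at -0.82 (quartiles of members -1.05 to -0.62) and 63 of 70 members stayed lower, which argues against that as the whole cause. A loss of short transcripts predicts a like fall in other genes of that length, with a bound of -0.51 set before the result, and 1000 draws of genes of matched length gave a median of -0.30 (quartiles -0.37 to -0.19), which argues against length as the main cause and leaves room for a part of it. Every ribosomal protein gene had a length. A lower share of ribosomal protein mRNA under fibrils is a hypothesis, and time in culture and the quality of the RNA, for which there is no measure here, stay open.

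OLIG2, S100B and TUBB3 were higher at 24 h and 96 h. Neural or glial cells in the treated cultures could bring them, along with their abundant transcripts, but of 15 such transcripts the 12 that were under 1 TPM at baseline reached at most 0.976 TPM (SLC1A2, 24 h), against 37.9 TPM of OLIG2 at 24 h and 22.5 TPM at 96 h. A first form of this test used all 15 and did not decide, and the bound at baseline was added after that result: the 3 set aside were SLC1A3 (28.8 TPM at baseline, 37.7 TPM at 24 h), PDGFRA (3.54 TPM and, at 96 h, 13.3 TPM) and GFAP (1.71 TPM and, at 24 h and 96 h, 1.62 TPM and 1.73 TPM). The bound scaled with the level of OLIG2 and was 3.79 TPM at 24 h. PDGFRA, a transcript of the oligodendrocyte lineage, was under it at 24 h (2.09 TPM) and above it at 96 h (13.3 TPM). SLC1A3 was above it at every time, baseline included. The 12 transcripts argue against cells that carry them as the source of OLIG2. Cells with PDGFRA at 96 h, expression in the microglia-like cells themselves and a rare cell type without these transcripts stay open. S100B, at 222 TPM at baseline, was already expressed before treatment.

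With 3 samples against 3 there are 10 splits, so the share of splits as large as the real one cannot fall under 0.1. In each gene comparison 1 split, the real one, gave the highest count. The real and the highest other counts of genes were 6086 and 2 at 4 h, 8014 and 1 at 24 h, 6339 and 1 at 96 h, 7818 and 0 between 4 h and 24 h, 5272 and 2 between 24 h and 96 h, and 7325 and 1 between 4 h and 96 h. For the lists they were 12 and 14 at 4 h, where 5 splits called as many, 18 and 17 at 24 h, and 17 and 15 at 96 h. Splits that mix the groups put part of the difference between them into the spread within groups. This alone keeps their gene counts low, so the gap to the real counts adds no support. The list test compares genes with genes. For the F test 10372 genes passed against a highest of 7102 in 100 regroupings of the 12 samples, and the classes held 6804 genes against 4795, each reached by 1 of the 100, the real one. Regroupings mix the groups in the same way as the splits, so these gaps add no support either.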
